A study of Mus musculus with 24 samples.

How the data were processed

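Poly(A) RNA was measured by RNA sequencing in 24 libraries from 8 mice, 4 with Phf6 deleted and 4 controls, per the labels. Each mouse gave 1 library from each of 3 sorted bone marrow populations, so every population held 4 deleted and 4 control libraries. The mice came from 4 litters with 1 deleted and 1 control mouse each, and the replicate number in the labels is the litter number. The strain label names a floxed Phf6 allele on the X chromosome and a Tie2-cre transgene, an endothelial and haematopoietic Cre driver, in the same words for both groups, so the labels do not say whether the control mice carried Cre.

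Per the labels' protocol, marrow was crushed from several bones, depleted of lineage-positive cells with antibodies against CD3, B220, GR1 and TER119, and sorted on cKIT, SCA1, CD150 and CD48. HSC and MPP libraries were made by SMART-Seq v4 amplification and Nextera XT, and HPC-1 libraries with a TruSeq Stranded kit. The kit is therefore confounded with the population wherever HPC-1 is set beside HSC or MPP, and HPC-1 levels were not compared with theirs; only the effects of deletion were. Paired-end reads of 80 bp were made on an Illumina NextSeq instrument.

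The deposited values are whole-number counts per gene, made by the authors with bcl2fastq and featureCounts on mm10, per the submitters' processing notes. The aligner, the annotation, the versions and the strand setting are not given in the sources used here. SMART-Seq does not mark the strand, so reads of overlapping or antisense genes cannot be told apart in HSC and MPP. The deposited table of the whole series was identical to the 24 files of the samples. It holds 27179 Entrez gene identifiers, of which 25275 were named from a RefSeq gene table of GRCm38.p6 and 18 from a GENCODE annotation, while 1886 stayed unnamed and were tested under their identifiers. Coordinates are those of the RefSeq table on GRCm38, the assembly that mm10 names. No total or other line without a gene was present.

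Total counts ran from 9658167 to 27786830 per library. No pair of libraries within a group agreed within sampling noise: the chi-square per degree of freedom of their counts lay between 16.7 and 248. Amplified reads are not independent molecules, so the counting intervals given for genes with very few counts cover counting error only.

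Each comparison was tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, the default expression filter (a count of 10, and 15 in total), and the robust quasi-likelihood test, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Levels are CPM, counts scaled to a common library total, on the TMM-scaled library sizes, given as mean ± SD. The 8 comparisons were deleted against control in each population, MPP against HSC within the controls and within the deleted mice, and 3 tests of whether the effect of deletion differed between populations. The 30 gene lists, the tests, the rule for named genes and the alternatives were chosen before the data were examined, apart from those named below as added.

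The lists were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2, with the preset inter-gene correlation of 0.01 and adjustment over the lists of a comparison. The same test with an estimated correlation was an alternative, as were a litter or mouse block and other size factors. For each list the number of members past the threshold is also given adjusted over the list alone. A list score is the mean over members of log2 CPM, centred on the 8 libraries of the population. Scores were compared by a 2-sided exact permutation of the genotype over the 8 mice, for which 0.0286 is the smallest p that 4 against 4 can give.

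Named genes are Phf6, then up to 12 genes in each direction with the lowest adjusted p past the threshold (10 for MPP against HSC in controls, none beyond the lists in deleted mice, and 5 for each test of a differing effect). Predicted genes with provisional symbols were left out of these ranks but counted. For each list described, up to 4 members past the threshold are named, and where none passed up to 2 with the lowest unadjusted p. A gene named in one comparison may have its values given in others.

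The numbers pair the samples by design: the labels give a shared litter for the deleted and control mouse of a number, and the same mouse for different populations. Deviations from the group means of same-numbered libraries correlated across genes at 0.01 to 0.06 in HSC, 0 to 0.15 in MPP and 0.08 to 0.38 in HPC-1, and between HSC and MPP of the same mouse at 0.15 to 0.32 in controls and 0.02 to 0.38 in deleted mice. The highest values with another number were 0.01 to 0.06, 0.06 to 0.14 and -0.07 to 0.12, and -0.09 to 0.01 and -0.03 to 0.1. Except between HSC and MPP of controls, some libraries correlated most with another number. Genes are not independent replicates. The fits without the block are the ones reported, and the blocked value is given where it changes a call or moves a count by more than 1.5 times.

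The alternatives chosen before the data were examined were no expression filter, RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom with quality weights, the block, a joint fit of HSC and MPP, and leaving out each library (or each mouse, for effects that span populations). Added after seeing the data were fits without libraries that stood apart on the first principal components, the list scores, camera with Phf6 left out of the lists, counts of calls with Phf6 left out of the count and of the adjustment, and a limma fit of the effect averaged over the 3 populations of each mouse. Counts of calls were compared with all 35 splits of the 8 mice, or of the 8 libraries, into 4 and 4.

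The fits were tested on simulated counts with the means, library sizes and spread of the real libraries and 200 genes changed. So many changed genes ease the adjustment, so the shares called may exceed those in real data with few calls. In HSC, over 13353 genes, 4.48% of genes changed 1.5-fold, 25.4% of those changed 2-fold and 78.8% of those changed 4-fold were called. In MPP, over 13606 genes, these shares were 1.49%, 19.4% and 83.3%, and in HPC-1, over 13584 genes, 32.8%, 65.7% and 90.9%. For MPP against HSC they were 16.4%, 50.7% and 75.8% over 13426 genes in controls, and 2.99%, 10.4% and 66.7% over 13563 genes in deleted mice. For the differences of effects, 2-fold changes were called in 8.96% (MPP and HSC, 14268 genes), 14.9% (HPC-1 and HSC, 14548 genes) and 10.4% (HPC-1 and MPP, 14575 genes). In the averaged fit, over 12843 genes, the shares were 14.9%, 68.7% and 87.9%. No counts were simulated there: the real averaged values, with the effect removed and the mice shuffled, were given upward shifts. These shares are therefore not comparable with the others. Camera recovered 10 of 10 raised lists in simulated HPC-1 data and called 0 of 20 unchanged ones. The simulated genes varied independently of one another, so this does not test lists of correlated genes; with the real libraries at least 1 list passed in 34 of 34 other divisions in HSC, MPP and HPC-1. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Some genes that the rule for named genes takes are not reported here; counts over named genes include them.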

Results

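RNA was profiled from 3 populations of mouse bone marrow stem and progenitor cells: haematopoietic stem cells (HSC), multipotent progenitors (MPP) and the restricted progenitors named HPC-1. They came from 4 mice with Phf6 deleted and 4 control mice, giving 6 groups of 4 libraries. Phf6 is an X-linked gene for a plant homeodomain finger protein of chromatin and the nucleolus that is mutated in human T-cell leukaemia. In controls the HSC libraries of litters 1 to 4 held 14490394, 11425005, 15413407 and 9658167 counts, the MPP libraries 16361061, 12385465, 22133635 and 12501905, and the HPC-1 libraries 27198793, 24790548, 16562824 and 27463270. In deleted mice the same litters held 20426904, 19854424, 13132902 and 15344444 counts in HSC, 18926212, 16047673, 12784013 and 21815852 in MPP, and 27786830, 18960366, 20337142 and 21509867 in HPC-1. The MPP library of deleted mouse 3 stood apart from the others in its make-up, with 9.339% of counts in its top 10 genes and 14710 genes detected.

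Phf6 (Entrez gene 70998, chromosome X, 52912214 to 52956961 on GRCm38) was lower in every library labelled deleted than in every control library of the same population. In HSC it was at 37.63, 53.99, 54.16 and 81.33 CPM in the deleted mice of litters 1 to 4 and at 186.2, 220.8, 244.1 and 223.8 CPM in their control littermates. In MPP the deleted libraries held 48.6, 67.36, 49.48 and 55.04 CPM and the controls 192.5, 170.2, 231 and 182.5 CPM. In HPC-1 the deleted libraries held 32.83, 23.99, 32.08 and 20.98 CPM and the controls 107.6, 142.1, 117.3 and 98.88 CPM. The counts cover the whole gene, so reads from exons outside the deleted part are included in these residual levels.

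**Figure D1:**
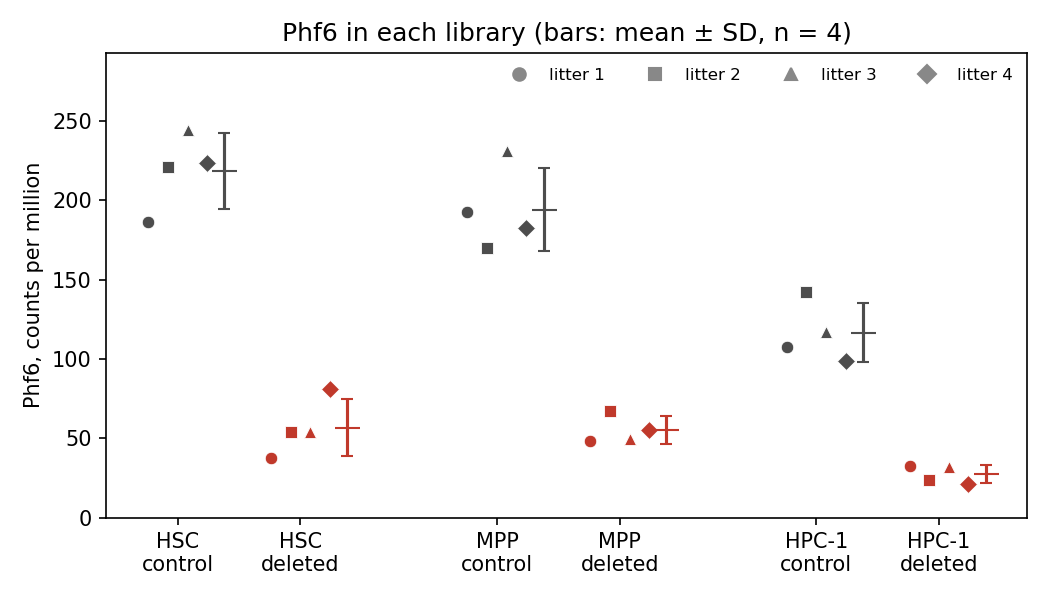
Phf6 in CPM for each of the 24 libraries, by population and genotype, with symbols for the litter and bars for the mean ± SD of 4 libraries. Deleted libraries lie between 20.98 and 81.33 CPM and controls between 98.88 and 244.1 CPM.

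The first comparison asked which genes differ between Phf6-deleted and control HSC. Phf6 itself fell from 219 ± 24 to 56.8 ± 18.1 CPM (SD, n = 4 each), a log2 fold change of -1.95 ± 0.22 (SE, edgeR adjusted p = 0.0211). It was the single gene of 13693 past the threshold. The gene group with the smallest camera p was the type I interferon response genes, the antiviral and signalling genes induced by interferon. Of these, 39 of 43 were higher in deleted HSC, with a median log2 difference of 0.39. None passed over all genes, and 9 rose when adjusted over the list alone, among them Rsad2, the antiviral enzyme viperin (1.03 ± 0.19), and Ifi44 (0.97 ± 0.20). The camera test of the list gave an adjusted p of 8.82e-12, and adjusted p = 0.319 with an estimated correlation.

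Class II antigen presentation genes were the other group placed higher in deleted HSC (8 of 9 members, median 0.48, camera adjusted p = 0.00153, and adjusted p = 0.415 with an estimated correlation). One member rose when adjusted over the list alone, and H2-Ab1 (0.83 ± 0.20) and H2-Aa (0.66 ± 0.24) had the lowest unadjusted p, 0.00158 and 0.0187. Without the HSC libraries of deleted mice 1 and 3 this list gave an adjusted p of 0.069. Cytosolic ribosomal protein genes lay slightly lower (median -0.16, 68 of 85 members, camera adjusted p = 0.00418, and adjusted p = 0.897 with an estimated correlation). Rpl5 was at 0.57 ± 0.29 and Rps29 at -0.78 ± 0.40, and the list gave 0.371 without deleted mouse 2, 0.169 without control mouse 4, and 0.784 in the upward direction without deleted mouse 4. Mature neutrophil and monocyte markers, of which GR1-positive cells were depleted before the sort, had a median of 0.58 in deleted HSC (14 of 16 members higher, Cxcr2 1.43 ± 0.67 and Mmp9 1.2 ± 1.07, or -0.37 without deleted mouse 4) and passed only in the litter-blocked camera test (adjusted p = 0.0056, against 0.103 without the block). The score of these markers was highest in deleted mouse 4 (1.95) and lowest in control mouse 3 (-2.17). Mitochondrially encoded genes passed likewise in the paired test alone (0.0309, against 0.115), with all 13 members lower. The other 25 lists did not pass with or without the block. Long-term HSC genes (0.457), HSC identity factors (0.782), S phase genes (0.482), p53 targets (0.115), NuRD complex genes (0.103) and genes near Phf6 on the X chromosome (0.818) were among them.

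The HSC call for Phf6 ended when any 1 of control libraries 1, 2, 3 or 4 or deleted libraries 2 or 3 was left out, with log2 fold changes between -2.17 and -1.78 over all 8 fits and adjusted p up to 0.253, and with the litter as a block (-1.99, adjusted p = 0.0606, no gene past the threshold). DESeq2 called 19 genes and limma-voom 1, and 528 genes had an unadjusted p under 0.05 in edgeR, where 685 would be reached by chance alone.

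The next comparison asked the same of MPP. Phf6 fell from 194 ± 26.3 to 55.1 ± 8.64 CPM (log2 fold change -1.82 ± 0.18, edgeR adjusted p = 0.00432), and 3 genes rose. Lin28b, which encodes an RNA-binding protein that blocks maturation of let-7 microRNAs and marks fetal stem cells (chromosome 10, 45376617 to 45486314), was at 6.69 ± 1.61 CPM in deleted MPP and at 0.0339 ± 0.0397 CPM in controls (n = 4 each, adjusted p = 0.00432). The deleted libraries held 453 Lin28b counts, 72 to 162 each, against 2 in the controls, a ratio of 215 with a 95% counting interval of 59.2 to 1780. Serpina3f, a serine protease inhibitor (chromosome 12, 104214544 to 104221129), rose from 15.2 ± 2.64 to 48.3 ± 6.63 CPM (1.66 ± 0.21, adjusted p = 0.0245). H2-Eb1, a class II beta chain (chromosome 17, 34305867 to 34316674), rose from 21.9 ± 4.45 to 66.9 ± 12 CPM (1.61 ± 0.22, adjusted p = 0.0417). Serpina3f and H2-Eb1 belong to families of related genes, and how any reads shared between members were counted is not known.

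Type I interferon response genes were higher in 42 of 43 members in deleted MPP (median log2 difference 0.52, camera adjusted p = 2.59e-18, and adjusted p = 0.473 with an estimated correlation). None passed over all genes and 19 rose when adjusted over the list alone. Mx1, a transcribed pseudogene in the annotation used, was at 2.50 ± 0.44 and Ifit3 at 1.94 ± 0.36, with adjusted p of 0.12 and 0.146. Class II genes were higher in 8 of 9 members (median 0.46, camera adjusted p = 3.08e-06, and adjusted p = 0.739 with an estimated correlation), with 1 risen over all genes, H2-Eb1, and 4 when adjusted over the list alone.

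**Figure D2:**
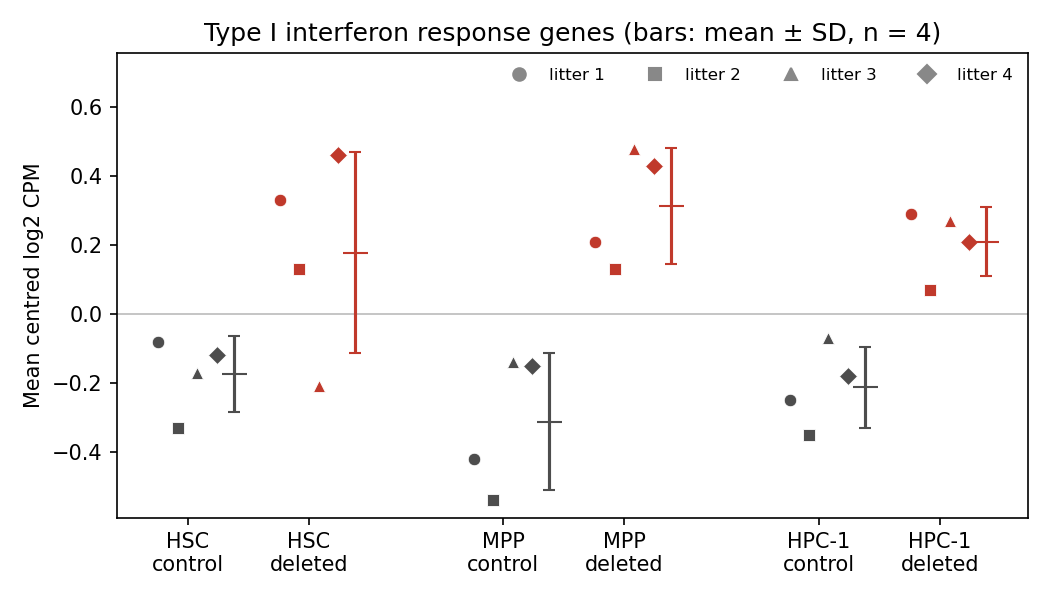
Score of the 43 type I interferon response genes (mean log2 CPM centred on the 8 libraries of each population) in each library, with symbols for the litter and bars for the mean ± SD of 4 libraries. The 4 deleted MPP and the 4 deleted HPC-1 libraries all lie above the controls, and in HSC deleted mouse 3 lies at -0.21, below 3 of the 4 controls.

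S phase genes lay lower in deleted MPP (25 of 31 members, median -0.40, camera adjusted p = 6.52e-06, and adjusted p = 0.861 with an estimated correlation), as did G2 and M phase genes (25 of 30, median -0.29, 0.000668, and adjusted p = 0.874 with an estimated correlation). Chaf1a, a chromatin assembly factor (-0.89 ± 0.26), Mcm3, a subunit of the replicative helicase (-0.68 ± 0.22), and the mitotic checkpoint genes Bub1b (-0.70 ± 0.31) and Bub1 (-0.70 ± 0.38) had the lowest unadjusted p, and no member of either list passed. Both calls ended without 1 library: without deleted mouse 4 the S phase list gave an adjusted p of 0.066 and the G2 and M list 0.776, and without deleted mice 3 and 4 they gave 0.173 and, in the upward direction, 0.871. Ribosome biogenesis genes (median -0.16, 35 of 47 lower, 0.00162, and adjusted p = 0.739 with an estimated correlation) gave 0.066 without deleted mouse 4. Bop1 was at -0.62 ± 0.19 and Rrp12 at -0.84 ± 0.28.

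Mitochondrially encoded genes were higher in 11 of 13 members of deleted MPP (median 0.75, camera adjusted p = 0.0214, and adjusted p = 0.874 with an estimated correlation), led by COX2 (0.92 ± 0.39) and COX3 (0.71 ± 0.33). They moved with deleted mouse 3, whose score was 1.25, and the adjusted p was 0.144, 0.349, 0.182 and 0.0777 without deleted mouse 2, deleted mouse 3, control mouse 3 or control mouse 4. Neutrophil and monocyte markers had a median of 1.19 (Chil3 1.55 ± 0.74, Ngp 1.63 ± 0.84) and passed only in the paired camera test (0.0143, against 0.115). Their score was 2.52 in deleted mouse 4 and -2.60 in control mouse 3. The TNF and NF-kB list did not pass (0.933), with the chemokine gene Cxcl10 (2.47 ± 0.39) risen when adjusted over the list alone and Vcam1 at -1.55 ± 0.46. PAF1 complex (0.889), Polycomb and SWI/SNF (0.933), glycolysis (0.207), T and NK (0.991), endothelial and stromal (0.709), erythroid (0.453) and megakaryocyte (0.842, median 0.02 with a downward test) lists did not pass either.

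The MPP count of 4 genes depended on the tool and on 1 library: DESeq2 called 105 genes, limma-voom 60, and edgeR without deleted library 3 called 22. It was 2, Phf6 and Lin28b, without any 1 of deleted libraries 1 or 2 or control libraries 1, 3 or 4. Without control library 2 or deleted library 4 it was 3. Over all 8 of these fits Serpina3f and H2-Eb1 each passed in only 1 (edgeR adjusted p up to 0.208 and 0.231), while Phf6 and Lin28b passed in 8. The litter block ended H2-Eb1 (1.62, adjusted p = 0.0572). In edgeR 1117 genes had an unadjusted p under 0.05, where 690 would be reached by chance alone, and genes are not independent.

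In HPC-1, 9 genes of 13907 passed. In edgeR 694 had an unadjusted p under 0.05, where 695 would be reached by chance alone. Phf6 fell from 116 ± 18.6 to 27.5 ± 5.9 CPM (-2.08 ± 0.16, edgeR adjusted p = 3.29e-05). Slc6a15, a sodium-coupled transporter of neutral amino acids (chromosome 10, 103367808 to 103419379), rose from 4.82 ± 1.56 to 18.6 ± 2.48 CPM (1.95 ± 0.25, adjusted p = 0.00856). Iigp1, an interferon-inducible GTPase (chromosome 18, 60373616 to 60392634), rose from 14.3 ± 3.55 to 38.6 ± 7.99 CPM (1.43 ± 0.19, 0.00964). Gm4951, a predicted GTPase gene of the same family that falls outside the naming rule and was chosen after its values were seen, rose by 2.66 ± 0.36 (0.00964). Reads of these 2 GTPase genes can be shared between relatives of the family. The immunoglobulin kappa segment Igkv12-44, a marker of B-lineage cells, had 178 counts in deleted and 2 in control libraries (ratio 96.2, 95% counting interval 26.3 to 801, adjusted p = 0.0336). It is one of many similar segments and had 0 counts in the deleted HSC and MPP libraries. The score of B and plasma cell markers in HPC-1 was higher in the deleted mouse of 4 of 4 litters (difference 0.36, exact permutation p = 0.429). The same score differed by -0.75 in HSC (higher in 1 of 4 litters) and by 0.28 in MPP (3 of 4).

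Besides Phf6, 4 genes fell in HPC-1. Col4a2, a chain of basement membrane collagen, fell from 66.5 ± 9.88 to 27.1 ± 7.01 CPM (-1.29 ± 0.18, adjusted p = 0.0107). Adgrl1, an adhesion G protein-coupled receptor, fell from 59.9 ± 13.6 to 27.4 ± 5.02 CPM (-1.13 ± 0.17, 0.0296), Sdsl, a serine dehydratase-like enzyme, from 25 ± 2.03 to 10.8 ± 2.63 CPM (-1.21 ± 0.20, 0.037), and Zfp532, a zinc finger gene, from 25.9 ± 3.97 to 10.8 ± 3.02 CPM (-1.26 ± 0.21, 0.037). With the litter as a block edgeR called 60 genes, among them Ifi44 (adjusted p = 0.0105), Rsad2 (0.0261), H2-Ab1 (0.0124), Mmrn1 (0.015) and Ccr2 (0.00147), and DESeq2 called 76 and limma-voom 24. With 1 library left out the count was 1 (deleted 1 or control 4), 2 (control 2), 3 (control 3), 4 (deleted 2) and up to 11 (deleted 4). Phf6 passed in all 8 of these fits, Slc6a15 in 6, Gm4951 in 5, Iigp1 in 4, Col4a2 in 3, Adgrl1 in 2, Zfp532 in 1, and Igkv12-44 and Sdsl in 0.

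Type I interferon response genes were higher in 42 of 43 members in deleted HPC-1 (median log2 difference 0.35, camera adjusted p = 2.4e-23, and adjusted p = 0.192 with an estimated correlation), and 21 rose when adjusted over the list alone, none over all genes. Ifi44 (0.79 ± 0.14, adjusted p = 0.0601) and Rsad2 (1.02 ± 0.20, 0.0988) had the lowest p of the list. Irf9, part of the interferon-activated transcription complex, was at 0.69 ± 0.19 in HSC, 0.48 ± 0.16 in MPP and 0.36 ± 0.10 in HPC-1, not past the threshold in any of them. Receptors of interferon and their signalling genes did not pass in any population (0.24, 0.357 and 0.379). Class II genes were higher in 8 of 9 members (median 0.59, camera adjusted p = 0.00817, and adjusted p = 0.513 with an estimated correlation), with H2-Ab1 at 0.59 ± 0.13 and H2-DMa at 0.20 ± 0.09.

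Another 6 lists passed in HPC-1 at the preset correlation, and 0 of the 8 did with an estimated one. HSC identity factors (median -0.14, 24 of 30 lower, camera adjusted p = 0.00817, and adjusted p = 0.513 with an estimated correlation) included Hoxa5 (-0.53 ± 0.17) and Prdm16 (-0.53 ± 0.21). Lymphoid priming genes (median -0.14, 20 of 25 lower, 0.00995, and adjusted p = 0.591 with an estimated correlation) included Gata3 (-1.13 ± 0.27), which fell when adjusted over the list alone, and Dntt (-0.36 ± 0.17). The T-ALL list lay lower (median -0.09, 19 of 26, 0.00995, and adjusted p = 0.221 with an estimated correlation), with 1 fallen over all genes, Phf6 itself, and 2 adjusted over the list alone, Phf6 and Gata3. Phf6 is a member of this list, and without it the list did not pass (median -0.08, 18 of 25 lower, 0.0741, and adjusted p = 0.437 with an estimated correlation). Megakaryocyte genes lay higher (median 0.35, 14 of 18, 0.00995, and adjusted p = 0.221 with an estimated correlation), with Mmrn1 (0.67 ± 0.14) risen adjusted over the list alone and F2r at 0.40 ± 0.14. Basophil and mast cell markers lay higher (median 0.53, 10 of 12, 0.00995, and adjusted p = 0.535 with an estimated correlation), with 2 risen adjusted over the list alone, Gzmb (2.09 ± 0.42) and Cma1 (4.81 ± 1.18). Gzmb is also a member of the T and NK cell list. The score of the basophil list differed by 0.87 (exact permutation p = 0.0857, adjusted p = 0.514 over the lists). Oxidative phosphorylation genes lay higher by little (median 0.07, 62 of 78, 0.00995, and adjusted p = 0.870 with an estimated correlation), with Ndufa9 at 0.18 ± 0.10 and Ndufb8 at 0.16 ± 0.10.

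Single HPC-1 libraries ended each of these 6 calls. Without control mouse 3 the adjusted p was 0.0871 for HSC identity, 0.105 for basophils and 0.339 for oxidative phosphorylation. It was 0.203 for lymphoid genes and 0.239 for oxidative phosphorylation without control mouse 1, 0.162 for lymphoid genes without deleted mouse 3, 0.0857 for megakaryocyte genes without control mouse 4, 0.0535 for the T-ALL list and 0.17 for oxidative phosphorylation without deleted mouse 4, and 0.0646 for basophils and 0.062 for oxidative phosphorylation without deleted mouse 1. Granulocyte-monocyte genes (median 0.32) and immediate early genes (median -0.11) passed only with the litter block (0.0017 and 0.00272, against 0.0644 and 0.283). The immediate early score was 2.18 and 2.55 in the deleted and control libraries of litter 4 and at most 0.07 in the other 6. Neutrophil and monocyte markers did not pass (0.379, Ccr2 1.22 ± 0.51, S100a8 0.76 ± 0.68).

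Several genes called in 1 population lay in the same direction in the others without passing there. Slc6a15 was at 1.10 ± 0.35 in HSC and 1.71 ± 0.30 in MPP, Iigp1 at 1.23 ± 0.25 and 1.24 ± 0.20, and Sdsl at -0.64 ± 0.19 and -1.46 ± 0.25. Serpina3f was at 0.96 ± 0.37 in HSC and 1.22 ± 0.35 in HPC-1. Lin28b was detected at 14.8 ± 8.47 CPM in deleted and 2 ± 1.42 CPM in control HSC (2.87 ± 0.70, adjusted p = 0.998), and at 2.53 ± 1.87 and 0.329 ± 0.584 CPM in HPC-1 (2.87 ± 1.16, adjusted p = 0.878).

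**Figure D3:**
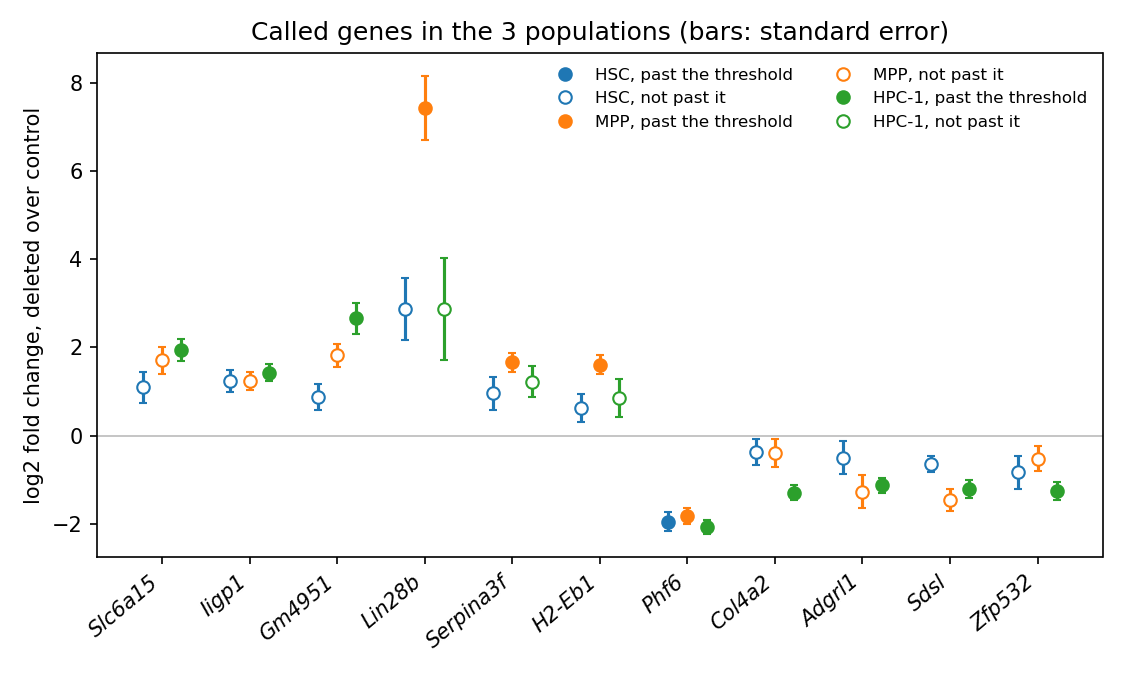
Log2 fold change of deleted over control with its standard error for genes past the threshold in at least 1 population, filled where they passed and open where they did not; Igkv12-44 is left out. Phf6 lies between -2.08 and -1.82 in the 3 populations, and the fitted Lin28b value in MPP (7.43) rests on 2 control counts.

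Whether the effect of deletion differed between populations was tested directly. No gene passed in edgeR for MPP against HSC (417 genes at an unadjusted p under 0.05, smallest adjusted p 0.978), for HPC-1 against HSC (518 and 0.501) or for HPC-1 against MPP (668 and 0.629). By chance alone 728, 748 and 745 genes would reach that unadjusted p. DESeq2 called 2, 12 and 7 genes and limma-voom 0 in each. The difference for Lin28b was 4.54 ± 1.10 between MPP and HSC and -4.59 ± 1.63 between HPC-1 and MPP, for H2-Eb1 0.99 ± 0.37 and -0.77 ± 0.46, and for Slc6a15 0.86 ± 0.44 between HPC-1 and HSC, with adjusted p of at least 0.915. None of these genes was shown to respond in 1 population only.

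Gene lists differed at the preset correlation for 8 lists between MPP and HSC, 0 between HPC-1 and HSC and 11 between HPC-1 and MPP, and for 0 with an estimated correlation. The MPP effect lay below the HSC effect for S phase genes (median difference -0.28, camera adjusted p = 3.13e-05, and adjusted p = 0.748 with an estimated correlation), G2 and M genes (-0.24, 0.00411) and ribosome biogenesis (-0.19, 0.000289), and above it for ribosomal proteins (0.24, 0.000289), mitochondrially encoded genes (0.95, 0.000289), class II (0.52, 0.0134), B cell markers (1.22, 0.0287) and the interferon response (0.18, 0.0287). With an estimated correlation all 8 had an adjusted p of 0.748 or more. Deleted mouse 4 ended the class II call when left out (0.141), B cell markers (0.112) and the interferon response (0.0755), deleted mouse 3 the mitochondrial call (0.452) and the interferon response (0.569), and deleted mouse 2 the class II call (0.104) and B cell markers (0.0539). Without deleted mouse 1 class II gave 0.0635, without control mice 1 and 2 in turn the interferon response gave 0.234 and 0.07, and without control mouse 3 G2 and M genes gave 0.057. The HPC-1 effect lay above the MPP effect for S phase (0.41, camera adjusted p = 1.66e-07) and G2 and M genes (0.23, 0.00393). It lay above it too for ribosome biogenesis (0.11, 0.0215), megakaryocyte genes (0.17, 0.0334) and basophil markers (0.0414, median -0.01). It lay below the MPP effect for the interferon response (-0.15, 0.00271), lymphoid genes (-0.58, 0.00105), HSC identity (-0.25, 0.00441), mitochondrially encoded genes (-0.78, 0.00393), long-term HSC genes (-0.27, 0.0215) and class II (-0.46, 0.0236). With an estimated correlation the 11 lists had an adjusted p of 0.3 to 0.795.

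Leaving out 1 mouse ended 7 of these 11 calls. Without deleted mouse 4 the adjusted p was 0.44 for G2 and M genes, 0.373 for ribosome biogenesis, 0.333 for class II and 0.184 for long-term HSC genes. Without deleted mouse 1 it was 0.0997 for long-term HSC genes, 0.06 for megakaryocyte genes and 0.0539 for ribosome biogenesis, and without deleted mouse 2 it was 0.143 for megakaryocyte genes, 0.625 for basophil markers and 0.0638 for mitochondrially encoded genes. Without deleted mouse 3 it was 0.144 for basophil markers and 0.144 for mitochondrially encoded genes. Of the controls, mouse 1 ended long-term HSC genes (0.0746) and class II (0.102), mouse 2 class II (0.0681), mouse 3 megakaryocyte genes (0.0989) and ribosome biogenesis (0.166), and mouse 4 long-term HSC genes (0.0833) and basophil markers (0.127). With the mouse as a block, oxidative phosphorylation genes passed between MPP and HSC (0.00901, against 0.109), and neutrophil markers (0.0052, against 0.25) and the T-ALL list (0.0461, against 0.0605) between HPC-1 and MPP.

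The number of lists past the threshold at the preset correlation was not beyond that of other divisions of the same mice into 4 and 4. These gave up to 16 lists in HSC, where the genotypes gave 3, up to 13 in MPP, where they gave 6, and up to 15 in HPC-1, where they gave 8.

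Across genes, deletion effects correlated at r = 0.32 between HSC and MPP (13321 genes), 0.25 between HSC and HPC-1 (12977) and 0.29 between MPP and HPC-1 (13123). The sign was shared by 62.4%, 57.3% and 58.5% of genes, and genes are not independent replicates. The same 8 mice gave all 3 populations, so differences between mice enter both effects: other splits of the mice gave medians of 0.22, 0.11 and 0.14 and highest values of 0.36, 0.27 and 0.29. The covariance was 0.0749, 0.0389 and 0.0489 for the real split, against medians of 0.0451, 0.0155 and 0.0199 and highest values of 0.085, 0.0459 and 0.0438 in the other splits.

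MPP were compared with HSC in the control mice, where 553 genes rose and 652 fell of 13636. Megakaryocyte and platelet genes were lower in MPP: 13 of 20 fell over all genes and 13 when adjusted over the list alone (median -1.94, camera adjusted p = 1.83e-14, and adjusted p = 0.0273 with an estimated correlation). They included the platelet integrin gene Itga2b (-2.81 ± 0.14), Treml1 (-4.58 ± 0.25), the platelet glycoprotein gene Gp1bb (-6.72 ± 0.51) and Gp5 (-3.10 ± 0.23). Cell cycle genes were lower too. Of 31 S phase genes 22 fell over all genes and 30 adjusted over the list alone (median -0.67, 1.99e-16, and adjusted p = 0.0676 with an estimated correlation), with Tyms (-0.85 ± 0.11) and E2f1 (-1.07 ± 0.15). Of 30 G2 and M genes 27 and 29 fell (median -1.05, 4.2e-26, and adjusted p = 0.0273 with an estimated correlation), with the mitotic kinase gene Aurkb (-1.46 ± 0.12) and Ube2c (-1.72 ± 0.14).

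Slamf1 encodes CD150, a marker the cells were sorted on, so its fall by 5.16 ± 0.26 on the log2 scale is no independent finding. Cavin2 (-6.96 ± 0.33), Mfsd2b (-4.46 ± 0.21), Tuba8 (-3.41 ± 0.21), Reep2 (-3.41 ± 0.25), Gata1, the erythroid and megakaryocyte transcription factor (-3.41 ± 0.25), and Aldh1a1 (-3.16 ± 0.24) also fell. Flt3, the receptor of early lymphoid and myeloid progenitors (3.36 ± 0.21), Cd34 (1.74 ± 0.12), Gfi1 (2.35 ± 0.16), P2ry14 (2.21 ± 0.18), Satb1 (3.05 ± 0.26), Cd82 (1.49 ± 0.13), Itgb5 (3.88 ± 0.35), Ltb (1.21 ± 0.11), Shisa8 (1.38 ± 0.13) and Vldlr (1.99 ± 0.19) rose.

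Lymphoid priming genes were higher in control MPP (7 rose and 1 fell of 18, and 9 and 1 adjusted over the list alone, median 0.77, camera adjusted p = 3.33e-06, and adjusted p = 0.191 with an estimated correlation). They included Flt3, Satb1, Lax1 (1.52 ± 0.20) and Il2rg (1.10 ± 0.17). Interferon response genes rose in 10 and fell in 1 of 43 members (15 and 1 adjusted over the list alone, median 0.38, 1.48e-06, and adjusted p = 0.313 with an estimated correlation), with Rtp4 (1.31 ± 0.18), Ddx58 (0.87 ± 0.15) and Irf9 (0.71 ± 0.14) up and Ifit2 (-0.77 ± 0.15) down. Interferon receptor and signalling genes rose in 7 of 15 (9 adjusted over the list alone, 8.29e-05, and adjusted p = 0.0481 with an estimated correlation), with Ifngr2 (1.14 ± 0.16), Il10rb (0.85 ± 0.16) and Ifngr1 (0.70 ± 0.14). TNF and NF-kB genes rose in 4 and fell in 2 of 26 (0.0124, and adjusted p = 0.313 with an estimated correlation), with Ccl4 (1.83 ± 0.24), Nfkbie (0.82 ± 0.15) and Ccl3 (3.21 ± 0.52) up and Tnfaip2 (-1.16 ± 0.23) down. Of 9 class II genes H2-Ob rose (1.68 ± 0.18; 3 rose adjusted over the list alone, 0.00108, and adjusted p = 0.313 with an estimated correlation).

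Ribosomal protein genes lay lower in control MPP (median -0.30, 5 of 85 fell over all genes and 4 adjusted over the list alone, camera adjusted p = 7.63e-07, and adjusted p = 0.701 with an estimated correlation), with Rps4l (-1.04 ± 0.21, a transcribed pseudogene in the annotation used), Rpl15 (-0.45 ± 0.12) and Rpl29 (-0.68 ± 0.18). Oxidative phosphorylation genes did likewise (median -0.27, 3 of 76 fell over all genes and 0 adjusted over the list alone, 2.47e-07, and adjusted p = 0.540 with an estimated correlation), with Cox6a1 (-0.60 ± 0.15), Cox6b2 (-0.84 ± 0.22) and Cox6b1 (-0.49 ± 0.14). Ribosome biogenesis genes (0.0295, and adjusted p = 0.701 with an estimated correlation; Nolc1 -0.60 ± 0.13) gave 0.109 to 0.119 without MPP controls 1 or 2 or HSC controls 3 or 4, and dendritic cell markers (0.0488, and adjusted p = 0.313 with an estimated correlation), where Flt3 alone rose, gave 0.0741 with the mouse as a block. The dendritic list gave 0.059, 0.118, 0.0874 and 0.166 without HSC control 1, MPP control 1, HSC control 3 or MPP control 4, and 0.0501 with RLE scaling. The long-term HSC list split, with 8 risen and 8 fallen of 29 (0.735; Ltb and Cd82 up, Vwf -3.91 ± 0.37 and Smtnl1 -3.11 ± 0.41 down). HSC identity genes did not pass as a list (0.161), with 11 of 31 fallen, among them Gfi1b (-1.93 ± 0.16). Granulocyte-monocyte genes (0.151) included 4 risen genes, Csf2rb (1.15 ± 0.25), Csf3r (0.93 ± 0.22), Cebpa (3.50 ± 0.83) and Spi1 (0.50 ± 0.13), and erythroid genes (0.264) 5 fallen, with Icam4 (-1.62 ± 0.21), Epor (-2.50 ± 0.34) and Zfpm1 (-0.84 ± 0.15). Neutrophil and monocyte markers had a median of -0.94 and passed with mitochondrially encoded genes in the paired test alone (0.000137 and 0.0283, against 0.151 and 0.0916). With the mouse as a block 2109 genes passed in place of 1205. Leaving out 1 library ended the call of Rpl15, Rpl29, Cox6a1, Cox6b2, Cox6b1, Csf3r, Cebpa or Spi1 in at least 2 of 8 fits (adjusted p up to 0.126).

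In the deleted mice the same comparison called 89 genes higher and 107 lower in MPP of 13887. Megakaryocyte genes fell in 12 of 20 members (13 adjusted over the list alone, median -1.86, camera adjusted p = 5.08e-18, and adjusted p = 0.00247 with an estimated correlation), with Vwf (-4.31 ± 0.30), Itga2b (-3.83 ± 0.28), Gp1bb (-8.53 ± 0.78) and Treml1 (-4.25 ± 0.43). S phase genes fell in 4 of 31 (20 adjusted over the list alone, median -0.96, 1.21e-15, and adjusted p = 0.212 with an estimated correlation), namely Chaf1a (-1.45 ± 0.25), E2f1 (-1.55 ± 0.30), Rrm1 (-1.26 ± 0.25) and Fen1 (-1.18 ± 0.24). G2 and M genes fell in 4 of 30 (25 adjusted over the list alone, median -1.35, 1.43e-16, and adjusted p = 0.253 with an estimated correlation), namely Aurkb (-1.76 ± 0.35), Ube2c (-1.80 ± 0.36), Plk1 (-1.64 ± 0.33) and Bub1b (-1.76 ± 0.37). Lymphoid genes rose in 5 of 17 (8 adjusted over the list alone, median 1.10, 7.15e-07, and adjusted p = 0.197 with an estimated correlation), with Flt3 (3.77 ± 0.35), Satb1 (3.46 ± 0.48), Il2rg (1.43 ± 0.21) and Lax1 (2.14 ± 0.33).

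Class II genes rose in 4 of 9 members between deleted HSC and MPP (6 adjusted over the list alone, median 1.22, camera adjusted p = 2.17e-06, and adjusted p = 0.212 with an estimated correlation): H2-Aa (1.29 ± 0.19), H2-Ob (1.91 ± 0.29), Cd74 (1.57 ± 0.26) and H2-Eb1 (1.26 ± 0.25). Interferon response genes had a median of 0.58 with 1 risen, Rtp4 (1.80 ± 0.30), and 6 adjusted over the list alone (1.09e-08, and adjusted p = 0.212 with an estimated correlation). Erythroid genes did not pass as a list (0.396, median 0.03 with a downward test) and held 3 fallen genes, Gata1 (-3.16 ± 0.39), Icam4 (-2.31 ± 0.36) and Epor (-2.60 ± 0.50). Ribosome biogenesis (3.51e-06), B and plasma cell (0.00688), dendritic (0.00958) and interferon receptor lists (0.0225, and 0.0582 with the mouse as a block) passed at the preset correlation and not with an estimated one (adjusted p = 0.212, 0.212, 0.212 and 0.599). The dendritic list gave 0.105 without HSC deleted 3 and 0.052 without MPP deleted 4, and the interferon receptor list 0.0507, 0.107 and 0.13 without MPP deleted 1, HSC deleted 3 or MPP deleted 4. Neutrophil and monocyte markers passed in the paired test alone (0.00308, against 0.165). The count of 196 fell to 71, 65, 54, 88, 79 and 73 without HSC deleted 1, MPP deleted 1, HSC deleted 2, MPP deleted 2, HSC deleted 3 or MPP deleted 4, and DESeq2 called 953 genes and limma-voom 795. Leaving out 1 library ended the call in 5 to 7 of 8 fits for the 8 cell cycle genes named, in 6 for H2-Eb1 and Epor, in 4 for Cd74, in 3 for Rtp4 and in 1 for H2-Aa, H2-Ob and Icam4. The lower count than in controls came with a larger spread (median SE 0.34 against 0.20) and is not itself a test of the genotype.

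**Figure D4:**
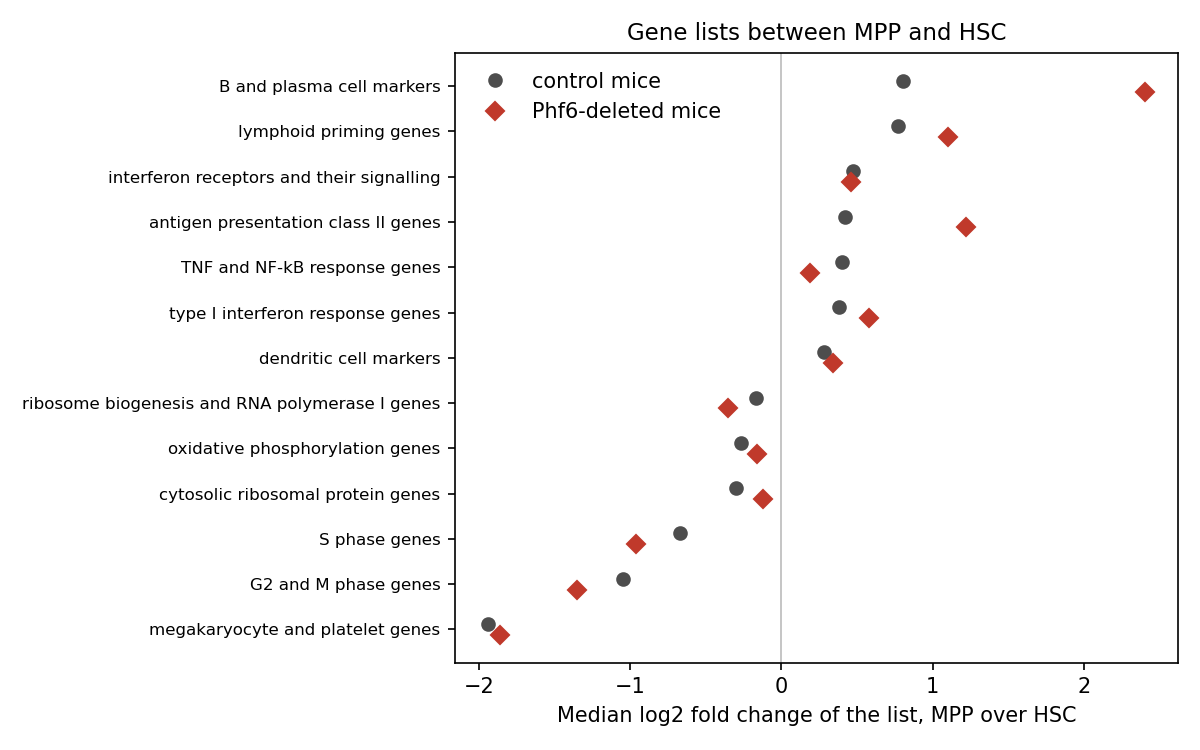
Median log2 fold change of MPP over HSC for each gene list past the threshold in controls or in deleted mice, with circles for control and diamonds for deleted mice. Megakaryocyte genes lie lowest in both (-1.94 and -1.86), and lymphoid genes lie at 0.77 and 1.10.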

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

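The tests of the immediate early and cell cycle patterns, the list scores, and the comparison of the interferon test with other divisions of the mice, were chosen after the results were seen.

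Type I interferon response genes lay higher in the deleted mice in all 3 populations. RNA of mature neutrophils and monocytes was tested as a source by adding the score of their markers to the fit: the lowest interferon median was 0.34, with medians of 0.34, 0.56 and 0.36 in HSC, MPP and HPC-1 against 0.32, 0.55 and 0.35 without the score, while the neutrophil medians went from 0.51, 0.79 and 0.14 to 0.02, 0.08 and -0.03. The medians in this paragraph are differences of log2 CPM, a scale other than that of the edgeR fold changes in the Results. The fall of the neutrophil medians follows from the fit, as the score is made of those genes. In HPC-1 these markers differed by only 0.14, so the score had little to remove there. In HSC and MPP the unmoved interferon medians argue against this RNA as the whole cause. Thinning every library to the lowest total, a test of sequencing depth, left medians of 0.34, 0.55 and 0.35. Thinning keeps the expected ratios between libraries, so it could hardly have lowered these medians and decides nothing about depth. The genotypes gave the smallest camera p of 35 divisions of the mice in each population (1 of 35, the smallest share possible), while 14, 20 and 19 of 34 other divisions also passed, with p as low as 3.86e-07, 1.09e-12 and 2.61e-23, and the populations share their mice. The score of the list, higher in the deleted mouse of 3, 4 and 4 of 4 litters, differed by 0.35, 0.63 and 0.42. The exact permutation p was 0.114, 0.0286 and 0.0286, with adjusted p = 0.489, 0.286 and 0.286 over the lists. The smallest p possible is 0.0286, so a lone list could not pass this adjustment whatever its effect. The adjusted values therefore cannot decide about chance, which stays open. Cre status of the controls stays open.

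G2 and M genes lay lower in deleted MPP, and without deleted mouse 4 their median was -0.04, against -0.39 with it on the same scale, which is in line with 1 mouse with low cell cycle genes and not all deleted mice. A fault of the MPP library of deleted mouse 4 alone is argued against by its other libraries: in 2 of 2 other populations its G2 and M score was also the lowest, -0.76 in HSC with the next at -0.07 and -0.3 in HPC-1 with the next at -0.07. S phase genes are another case: their median stayed at -0.27 without this mouse, against -0.44, with a camera adjusted p of 0.066. Their score was lower in the deleted mouse of all 4 litters (difference -0.4, exact permutation p = 0.0857, adjusted p = 0.367), so it stays open whether 1 mouse or all deleted mice account for it. Why mouse 4 was low was not tested.

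Immediate early genes were high in both HPC-1 libraries of litter 4, at scores of 2.18 and 2.55 with the other 6 between -1.57 and 0.07. A response of the 2 mice that all their stem and progenitor cells share was tested in their HSC and MPP libraries, of which 0 of 4 lay above the other litters. Handling of these HPC-1 samples and a response of HPC-1 cells alone were not tested and stay open.

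A sample far from the other 3 of its group was found in 2 of 88 groups of 4, where chance gives about 1 in 20. Adgrl1 was at 19.92 CPM in HPC-1 of deleted mouse 4, with the other deleted libraries at 29.57 to 30.46 CPM. The score of neutrophil and monocyte markers was -2.6 in MPP of control mouse 3, with the other controls at 0.17 to 0.55. The effect of deletion differed between populations, by the camera test of the difference at its preset correlation, for 8 gene lists between MPP and HSC and for 11 between HPC-1 and MPP. With an estimated correlation 0 lists passed in either, and 5 of 35 divisions of the mice gave at least 11 lists for HPC-1 minus MPP (highest other 12).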

How the results depend on the processing

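The fits without deleted mice 1 and 3 (HSC), without deleted mice 3 and 4 (MPP), without litter 3 (HPC-1) and without mouse 3, camera with Phf6 left out of the lists, and the adjustment without Phf6, were chosen after the data were seen.

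Phf6 kept its direction in all 47 alternatives and its call in 39; the 8 others were in HSC. Named genes kept direction and side of the threshold in 235 of 240 alternatives in HSC, 311 of 352 in MPP, 354 of 420 in HPC-1, 825 of 868 for MPP against HSC in controls and 278 of 360 in deleted mice. Besides Phf6, none of those in HSC and few in MPP and HPC-1 were called, so these shares mostly count genes that stayed uncalled. Called genes were less stable: in MPP, Serpina3f and H2-Eb1 each kept the call in 1 of 8 fits with 1 library left out, and Lin28b in 8. On simulated counts a 2-fold change was recovered for 25.4% of genes in HSC, 19.4% in MPP and 65.7% in HPC-1, so low counts of calls leave changes of that size undetected. For the changed results below, the cause was not tested.

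In HSC the 1 called gene became 19 with DESeq2, 2 in the joint fit of HSC and MPP, 0 without deleted mice 1 and 3, and 0 to 1 with 1 library left out. Phf6 was at -1.68 without deleted mice 1 and 3 and between -2.17 and -1.78 with 1 library left out. Mmp9 turned to -0.37 without HSC deleted 4 and ran up to 1.69. In MPP the 4 genes became 105 with DESeq2, 60 with limma-voom, 17 in the joint fit, 21 without deleted mice 3 and 4, and 2 to 22 with 1 library left out. In HPC-1 the 9 genes became 20 with no low-count filter, 76 with DESeq2, 24 with limma-voom, and 1 to 11 with 1 library left out. With Phf6 left out of the count and of the adjustment, 0 genes were called in HSC, 2 in MPP (H2-Eb1 at an adjusted p of 0.0555) and 8 in HPC-1. The 196 genes of MPP against HSC in deleted mice became 953 with DESeq2, 795 with limma-voom, and 54 to 208 with 1 library left out. The 1205 in controls ran from 832 to 1338. DESeq2 called 2, 12 and 7 genes for the differences MPP minus HSC, HPC-1 minus HSC and HPC-1 minus MPP.

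With the litter or mouse as a replicate block, HSC held 0 called genes (Phf6 -1.99), HPC-1 60 and MPP against HSC in controls 2109, and 5 lists passed in HSC in place of 3. The block changed the calls of single genes and lists that are given beside them and no other call of a named gene or of a list past the threshold without it.

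With an estimated correlation the lists past the threshold became 0 in HSC, MPP and HPC-1, 3 for MPP against HSC in controls, 1 in deleted mice, and 0 for each difference of effects. In HSC they were 7 without deleted mice 1 and 3. In HPC-1 they were 7 in place of 8 with Phf6 left out of the lists, as the T-ALL list did not pass without it (0.0741). With 1 library or mouse left out they ran from 2 to 7 in HSC, 6 to 8 in MPP, 7 to 11 in HPC-1, 11 to 14 and 9 to 13 for MPP against HSC in controls and deleted mice, and 5 to 8, 0 to 5 and 8 to 11 for the differences. The ribosomal protein list in HSC turned upward without HSC deleted 4 (0.784) and reached 5.3e-08 without HSC deleted 3. The G2 and M list in MPP turned upward without deleted mice 3 and 4 (0.871). The correlations of effects ran over 0.25 to 0.37, 0.17 to 0.26 and 0.22 to 0.31 for HSC with MPP, HSC with HPC-1 and MPP with HPC-1.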

Other observations

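The effect averaged over the 3 populations of each mouse, the list scores, the divisions of the mice for the averaged effect, the covariance of effects and the counts without Phf6 were chosen after the data were seen; the other divisions were chosen before.

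Averaging the effect of deletion over HSC, MPP and HPC-1 of each mouse, limma called 5 of 12843 genes, with 1081 at an unadjusted p under 0.05. Phf6 fell (-1.97 ± 0.11, adjusted p = 0.000402) and Slc6a15 rose (1.59 ± 0.16, 0.0358; 1.18, 1.63 and 1.97 in the 3 populations). Gm4951 rose (1.79 ± 0.20, 0.0413). Slc27a3, a gene of the fatty acid transport protein family, fell (-1.92 ± 0.20, 0.0358), with -3.14 in HSC, -2.29 in MPP and -0.32 in HPC-1, and Ldlrad4, an inhibitor of TGF-beta signalling, rose (1.01 ± 0.12, 0.0413), with 2.58, 0.33 and 0.12. All 5 had the same direction in 4 of 4 litters. The number was 1, Phf6, with the replicate block, 1 to 5 with 1 mouse left out, 10 without HSC, 2 without MPP and 3 without HPC-1. With Phf6 left out of the count and of the adjustment 0 genes passed, the other 4 each at an adjusted p of 0.0516. Of 35 divisions of the mice 1 gave as many as 5 (highest other 0), a result that the deleted gene alone brings about. Without Phf6 the count was 0, which every division reaches (35 of 35, highest other 0). The divisions therefore decide nothing about the other 4, for which chance stays open.

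The mean score of the interferon response genes over the 3 populations was higher in the deleted mouse of 4 of 4 litters (difference 0.47, two-sided exact permutation p = 0.0286, the smallest possible, adjusted p = 0.429 over the lists). That of class II genes was higher in 4 of 4 litters too (difference 0.53, exact permutation p = 0.0286, adjusted p = 0.429). A lone list at this smallest p could not pass the adjustment, here or in single populations, so the adjusted values decide nothing about chance. In single populations the scores of the genotypes did not overlap, at exact permutation p = 0.0286 and adjusted p = 0.286, for 3 lists in HSC, all lower: p53 targets (-0.47), NuRD complex genes (-0.19) and the T-ALL list (-0.2, or -0.12 without Phf6, exact permutation p = 0.0286). In MPP they did not for NuRD complex genes (-0.15), interferon response genes (0.63) and class II genes (0.78), and in HPC-1 for HSC identity factors (-0.21), megakaryocyte genes (0.38) and interferon response genes (0.42). The p53 target score in MPP (-0.16, 0.0857) and HPC-1 (-0.13, 0.629) and the NuRD score in HPC-1 (0.03, 0.714) overlapped between genotypes. HSC identity factors went the other way in MPP (0.07, higher in 4 of 4 litters, exact permutation p = 0.0571) and were at -0.06 in HSC. Megakaryocyte genes were at -0.06 in MPP and 0.11 in HSC. Without Phf6 the T-ALL list was at 0.05 in MPP and -0.09 in HPC-1. These scores overlapped too.

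The number of genes was reached by 1 of 35 divisions in MPP (4 genes, highest other 0) and in HPC-1 (9 genes, highest other 1), counts that include the deleted gene. Without Phf6 the genotypes still gave more genes than any other division. In MPP there were 2 genes (1 of 35, highest other 0) and in HPC-1 8 genes (1 of 35, highest other 1). That share is the smallest possible, the count was chosen after the data were seen, and most divisions do not part the litters. Chance is therefore not excluded by it. For MPP against HSC in controls (1205, 1 of 35, highest other 0) and in deleted mice (196, 1 of 35, highest other 0) the other divisions mix 2 sorted populations in each group, and the sort itself sets these populations apart, so these counts decide nothing about chance. Chance could not be excluded in HSC (1 gene, 2 of 35, highest other 1). In HSC without Phf6 (highest other 1) and for the differences of effects (highest other 1, 2 and 0) 0 genes were called. All divisions reach that count (35 of 35 in each), so it decides nothing about chance. Among the 8 divisions that part all 4 litters, the highest other was 0 in HSC, MPP and HPC-1, and 8 divisions are too few for a share under 0.05.

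For the number of gene lists, only MPP minus HSC gave more than every other division (8 lists, 1 of 35 divisions as many, highest other 5), at the preset correlation. That number was 0 with an estimated correlation and 5 without deleted mouse 4, a number that other divisions reach. It is 1 of 8 comparisons and reaches only the smallest share possible, and most divisions do not part the litters. Chance is therefore not excluded by it. Chance could not be excluded in HSC (3 lists, 33 of 35, highest other 16), MPP (6, 30 of 35, 13), HPC-1 (8, 18 of 35, 15) or HPC-1 minus MPP (11, 5 of 35, 12). For MPP against HSC in controls (12, 7 of 35, 14) and in deleted mice (10, 11 of 35, 15) the divisions again mix the sorted populations and decide nothing. For HPC-1 minus HSC 0 lists passed, a number that all divisions reach (35 of 35, highest other 11), which decides nothing either. Parting all 4 litters, the highest others were 7, 9 and 8 lists in HSC, MPP and HPC-1. In HSC, MPP and HPC-1 at least 1 list passed in 34 of 34 other divisions. For the correlations of effects chance could not be excluded: 0.32 for HSC and MPP (4 of 35 as large, highest other 0.36), 0.25 for HSC and HPC-1 (2 of 35, 0.27) and 0.29 for MPP and HPC-1 (2 of 35, 0.29). The covariance was as large in 3 of 35 divisions for HSC and MPP (0.0749, highest other 0.085), in 2 for HSC and HPC-1 (0.0389, 0.0459) and in 1 for MPP and HPC-1 (0.0489, 0.0438).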
